A study of Bos indicus with 12 samples.

How the data were processed

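Blood RNA of 12 Bos indicus cows was sequenced, 3 in each of 4 groups made by breed (Gir or Shweta Kapila) and by milk yield class (high or low). The yield classes come from lactation records and were set within each breed, per the labels. The milk yields themselves are not given in the sources used here. Each library comes from a separate cow, so the p-values measure the spread between cows, pooled over the 4 groups. The labels name both peripheral blood mononuclear cells and the PAXgene Blood RNA kit, which takes in whole blood, so lists of granulocyte, platelet and erythroid markers were tested beside the mononuclear ones. The library kit marks strand and removes ribosomal RNA, per the labels' protocols.

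The deposited values are expected counts per gene, of which 57.0% are not whole numbers (tolerance 1e-06), with no scaling applied by the authors as far as the column totals show. Trimmomatic and FastQC are named, with no versions, per the submitters' processing notes. The aligner, the counting program, its strand setting, the genome build and the annotation are not given in the sources used here. Reads shared between near-identical genes, and reads of overlapping or antisense genes, can therefore be split in unknown ways. This limit applies to ribosomal protein genes, granzymes, interferon-induced families and Fc receptor-like genes in particular. All sample columns of the table were used.

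The table holds 26229 gene identifiers, of which 2852 had no count in any library. Symbols were taken by identifier from a RefSeq gene table for the assembly NIAB-ARS_B.indTharparkar_mat_pri_1.0, used for names and gene span only, and 22754 identifiers (86.8%) matched. No coordinates are given, since the build of the counts is not stated. Haemoglobin genes and mitochondrially encoded genes carry no name in these tables. A set of 37 identifiers with 7 or 8 digits, where the others have 9, matched no name and held between 4.54% and 13.1% of the counts of a library. They were kept in the counts and their share was followed as a library property. Of the 37, 13 have 7 digits and 24 have 8. Whether they are the mitochondrially encoded genes, which carry no name here, was not tested.

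Expected counts were rounded to whole numbers and analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with groups (minimum count 10, minimum total 15), which left 15420 genes, of which 11894 had a gene symbol, 2118 a LOC number and 1408 no match. TMM scaling was followed by a robust quasi-likelihood fit with a mean for each of the 4 groups over all 12 libraries, so that all groups share an estimate of the spread. The common biological coefficient of variation was 0.381. Tests were 2-sided, with Benjamini-Hochberg adjustment and a false discovery rate of 0.05. The 5 comparisons were high against low yield in Gir, the same in Shweta Kapila, the mean of both yield differences, the Gir difference minus the Shweta Kapila difference, and Gir against Shweta Kapila. Log2 fold changes are given with standard errors (SE) and normalised counts (CPM) as mean and standard deviation (SD) over cows. Total counts ran from 14.2 to 27.2 mega-counts (M), so a count of 10 equals 0.704 CPM in the smallest library and 0.368 CPM in the largest.

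Gene lists of blood cell types and pathways were fixed before the data were examined. Lists can share members, and BLNK belongs to both the B cell and the dendritic list. Of 32 lists, 30 had at least 3 members past the filter. Lists for gamma-delta T cells, with 2 members, and for mitochondrially encoded proteins, with 0, were not tested. Symbols with no match in the table or under the filter dropped out of the other lists. Past the filter were 9 of 15 monocyte, 12 of 19 NK, 16 of 27 neutrophil and 33 of 45 interferon symbols. For milk synthesis these were 23 of 41, and for class II antigen presentation 4 of 18. Lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation between genes of 0.01, adjusted over the 30 lists of a comparison. Camera with an estimated correlation and fry were run beside it. A call at the preset correlation is described as higher or lower for a list, and the unadjusted p-value with an estimated correlation stands beside it; no list was called with an estimated correlation. The mean log2 CPM of each of the 10 cell type lists was compared between groups by exact permutation, which cannot go below p = 0.1 for 3 cows against 3. Principal components were computed from log2 CPM of the tested genes. Members of each list that correlate with component 1 over the 12 cows were counted after the data had been seen (2-sided, unadjusted p under 0.05). Component 1 is made from these same genes, and the share of all genes past that bound was not counted. These counts therefore describe the lists and do not test them. Correlations and permutation tests used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and plots matplotlib 3.10.9.

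Named genes were chosen by a rule fixed in advance. In each comparison these are the 10 genes of largest change per direction among those past the false discovery rate, with average log2 CPM of at least 1 and no overlap between the cows of the 2 sides (a condition not set for the interaction). Where fewer than 5 passed in a direction, the 5 symbols of lowest p in that direction were taken and are given as values that did not pass. Up to 4 members of each list with the lowest p and up to 2 unnamed identifiers per direction were added. Genes outside the rule are marked as chosen after their values were seen. Some genes that met the rule are not reported here.

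Alternatives fixed in advance were relative log expression and upper-quartile scaling, no filter and a stricter filter (CPM of at least 1 in 6 libraries), DESeq2 1.42.0, limma-voom with sample quality weights, a log2 fold change of at least 1, the replicate number as a block, a fit on each breed alone, a prior count of 0.5, a median in place of a mean for list scores, and each cow left out in turn. Chosen after the data were seen were fits without the 37 unnamed identifiers, with counts thinned to the smallest total, without the 3 libraries of over 22 M counts, and with the log2 total count or the log2 share of the unnamed identifiers as a covariate. The procedure was tested on simulated data for the real means and library sizes of 15420 genes, with 200 genes changed. For the Gir yield comparison it called 10% of genes changed 2-fold and 73% of those changed 4-fold. For the yield difference over both breeds these shares were 28% and 94%, and for the breed comparison 24% and 90%. The simulated genes were independent, with the same spread in every group, and changed genes were drawn above a minimum mean CPM. The shares need not carry over to the real cows, whose spread differs between groups.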

Results

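Blood transcriptomes were measured in 12 cows of 2 indigenous Indian breeds, Gir, a zebu dairy breed, and Shweta Kapila. Each breed contributed 3 high-yielding and 3 low-yielding cows, and the stated aim was to relate gene expression in blood to milk production. Total counts per library, in mega-counts (M), averaged 18.1 ± 1.65 M in high-yielding Gir, 17.6 ± 3.23 M in low-yielding Gir, 20.7 ± 5.65 M in high-yielding Shweta Kapila and 21.7 ± 4.75 M in low-yielding Shweta Kapila cows (mean ± SD, n = 3 each). The 3 largest libraries were Shweta Kapila high 3 (27.2 M), low 1 (25.9 M) and low 2 (22.7 M). Within every group each pair of libraries differed by far more than sampling noise (chi-square per degree of freedom 35.1 to 397), so no library is a copy of another in its group.

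Principal component 1 held 37.7% of the variance and component 2 held 14.6%. Gir cows stayed close together on component 1, at −16.0 ± 14.3 for high and −11.7 ± 17.8 for low yield (mean ± SD, n = 3 each). Shweta Kapila cows spread far more, at −9.96 ± 54.0 for high and 37.7 ± 82.1 for low yield. The gene tests share an estimate of the spread over all groups, and the median SE for yield was 0.386 in either breed. SEs and p-values may therefore be too large for Gir and too small for Shweta Kapila. Shweta Kapila high 3 (45.6) lay beside low 1 (104) and low 2 (63.7), and low 3 (−54.3) lay beside high 1 (−62.4) and high 2 (−13.0). Over the 12 cows the component 1 score correlated with the total count (Pearson r = 0.834, permutation p = 0.00142, adjusted p = 0.00426 over 6 relations; Spearman rho = 0.734, permutation p = 0.00869, adjusted p = 0.0261; r = 0.718 without the 2 libraries of most extreme total). It correlated as well with the share of counts on the 37 unnamed short identifiers (r = 0.921, permutation p = 5e-05, adjusted p = 0.0003; rho = 0.846, permutation p = 0.00096, adjusted p = 0.00576; r = 0.751 without the 2 farthest libraries). Within Gir the relations did not pass (r = 0.450 for the total, exact permutation p = 0.372; r = 0.523 for the share, exact permutation p = 0.278). Within Shweta Kapila r was 0.888 for the total (exact permutation p = 0.0472, adjusted p = 0.0708) and 0.950 for the share (exact permutation p = 0.0139, adjusted p = 0.0278). Spearman rho was 0.771 for the total (exact permutation p = 0.103, adjusted p = 0.154) and 0.943 for the share (exact permutation p = 0.0167, adjusted p = 0.0333).

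**Figure D1:**
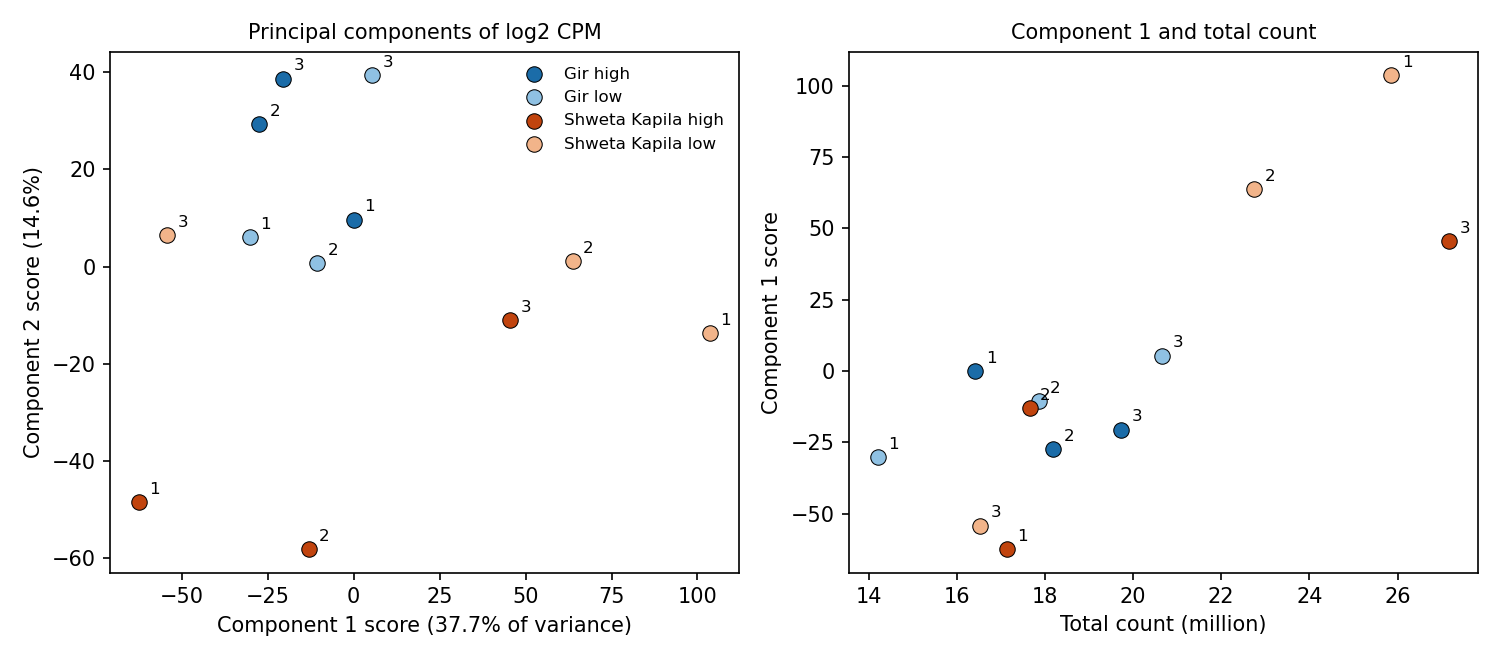
Left, component 1 and component 2 scores of the 12 libraries from log2 CPM, coloured by group and numbered by cow; right, component 1 score against total count in M (mega-counts). Shweta Kapila high 3, low 1 and low 2, the libraries of over 22 M counts, have the highest component 1 scores (45.6, 104 and 63.7).

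In Gir cows, PDK4 and CPT1A were among the 5 named genes of lowest p on the side higher with high yield. PDK4 (identifier 109558225), the kinase that inhibits pyruvate dehydrogenase, stood at 49.6 ± 15.8 CPM in high-yielding and 9.52 ± 3.20 CPM in low-yielding cows (mean ± SD, n = 3 each), a log2 fold change of 2.38 ± 0.49 (SE). CPT1A (identifier 109554147), the enzyme that commits long-chain fatty acids to mitochondrial oxidation, stood at 109 ± 7.82 against 47.3 ± 14.3 CPM (log2 fold change 1.20 ± 0.32). GJB2, a connexin, C23H6orf132 and LYPD3 had the next lowest p-values on the higher side, with log2 fold changes of 2.82 ± 0.69, 2.32 ± 0.61 and 1.31 ± 0.36. On the lower side stood NRIP3 (−1.63 ± 0.39), CD24, a surface glycoprotein of developing B cells and granulocytes (−1.33 ± 0.35), ACTA2, smooth muscle actin (4.42 ± 0.949 against 31.6 ± 34.8 CPM, mean ± SD, n = 3 each; −2.84 ± 0.76), PLD2, a phospholipase D (−2.85 ± 0.81), and KIF7, a kinesin of the primary cilium (−0.95 ± 0.28). Without low 2 ACTA2 was at −1.39 and C23H6orf132 at 3.00. All of these but PLD2 separated the 3 high-yielding from the 3 low-yielding cows without overlap. Chance gives this for 10% of unselected genes, but these were taken by lowest p, so the separation is no further support. None of the 15420 genes passed edgeR's quasi-likelihood test in Gir (0 calls, lowest adjusted p = 1), and 291 had an unadjusted p under 0.05 (181 higher, 110 lower) where uniform p-values would give 771. DESeq2 and limma-voom with sample weights each called 1 gene, PDK4 (adjusted p = 0.0144 and 0.0427). Adjusted over the list alone, PDK4 and CPT1A passed among the 33 members of the fatty acid and triglyceride list, which as a whole was not called (camera adjusted p = 0.0823, 24 members higher and 9 lower).

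Monocyte genes were higher in high-yielding Gir cows. Of 9 measured members 8 were higher (median log2 fold change 0.70), among them the lipopolysaccharide co-receptor CD14 (49.3 ± 11.6 against 26.3 ± 4.84 CPM, mean ± SD, n = 3 each; log2 fold change 0.91 ± 0.38) and the growth factor receptor CSF1R (0.77 ± 0.38). Camera called the list at the preset correlation (adjusted p = 4.91e-05) and with each cow left out, but not with an estimated correlation (unadjusted p = 0.0329, adjusted p = 0.359). None of the 5 Gir lists below was called with an estimated correlation either (adjusted p of at least 0.359). The mean score of the list was 0.62 log2 units higher, at the smallest p the exact permutation test allows (p = 0.1, adjusted p = 0.667 over 10 lists). Inflammatory genes were called higher (14 of 25 members, median 0.06; adjusted p = 0.0225, unadjusted p = 0.0202 with an estimated correlation), with IL12B at 3.00 ± 0.81 (3.77 without low 3), the interleukin 1 antagonist IL1RN at 0.81 ± 0.32 and the superoxide dismutase SOD2 at 1.04 ± 0.43. Pattern recognition receptors (15 of 20, median 0.24; adjusted p = 0.0193, unadjusted p = 0.115 with an estimated correlation) and heat shock genes (17 of 22, median 0.14; adjusted p = 0.0283, unadjusted p = 0.301 with an estimated correlation) were called higher as well. The heat shock list was led by CRYAB, a small chaperone at 1.23 ± 0.659 against 0.235 ± 0.215 CPM (log2 fold change 2.30, and 2.93 without low 2). Interferon response genes were called lower (28 of 33, median −0.14; adjusted p = 0.00394, unadjusted p = 0.25 with an estimated correlation), including IFI44 (−0.78 ± 0.31) and OAS2 (−1.21 ± 0.66, and −2.02 without high 3). T cell genes were called lower (18 of 20, median −0.20; adjusted p = 0.0385, unadjusted p = 0.317 with an estimated correlation), with BCL11B at −0.60 ± 0.30 and TCF7 at −0.31 ± 0.23. No member of these 6 lists passed the gene test over all genes or adjusted over the list alone (0 calls).

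Apart from monocytes, each of these Gir list calls ended with some of the cows left out in turn. The inflammatory call ended without high 3 (adjusted p = 0.0647) or low 2 (0.0662), that of pattern recognition receptors without high 3 (0.187) or low 2 (0.317), and that of interferon genes without high 1 (0.964) or low 3 (0.173). The heat shock call ended without high 1 (0.112), high 3 (0.0647), low 1 (0.127) or low 2 (0.0619). It also ended with thinned counts (0.0831) and with the log2 total count (0.0911) or the share of the unnamed identifiers (0.0923) as a covariate. The inflammatory call ended as well without the 3 libraries of over 22 M counts (0.0507) and with the share covariate (0.063). The T cell call ended without Gir high 2 (0.139), high 3 (0.187), low 1 (0.176) or low 2 (0.65), and without Shweta Kapila high 2 (0.0522) or high 3 (0.0528). The number of called lists, 6, became 3 without high 3 or low 2 and 10 without high 1 or low 3.

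**Figure D2:**
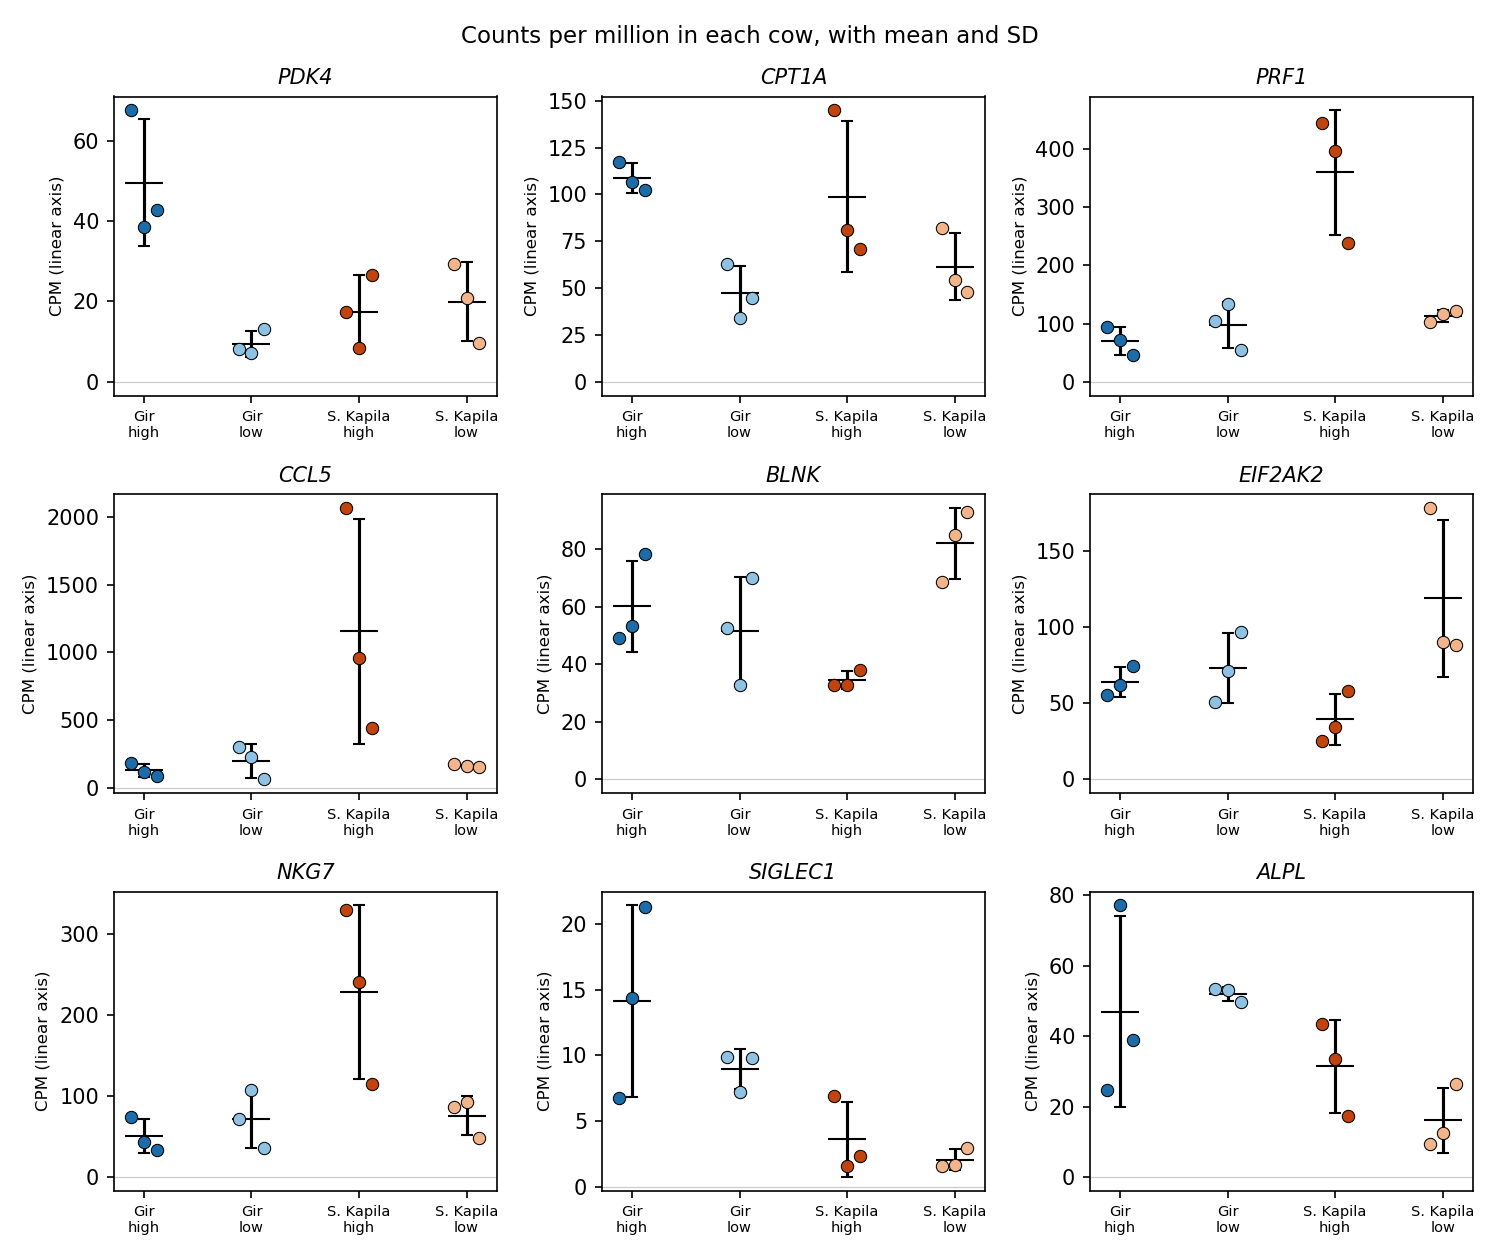
CPM on linear axes for 9 named genes in each cow (points), with the group mean (bar) and SD (whiskers), n = 3 cows per group. PDK4 is highest in high-yielding Gir cows (49.6 ± 15.8 CPM), while PRF1 and CCL5 are highest in high-yielding Shweta Kapila cows (359 ± 107 and 1156 ± 832 CPM).

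In Shweta Kapila cows, the 5 named genes of lowest p on each side for yield included PRF1 and CCL5 on the higher and BLNK on the lower side. PRF1 (identifier 109553933), the pore-forming perforin of cytotoxic cells, stood at 359 ± 107 CPM in high-yielding and 113 ± 9.81 CPM in low-yielding cows (mean ± SD, n = 3 each; log2 fold change 1.67 ± 0.36). CCL5 (identifier 109574467), a chemokine of activated T cells, stood at 1156 ± 832 against 161 ± 10.5 CPM (2.85 ± 0.61, and 2.13 without high 1). RGS9, a regulator of G protein signalling (2.19 ± 0.36), SLC14A1, the urea transporter of red cells (2.25 ± 0.39), and BEGAIN (3.73 ± 0.68, and 2.80 without high 2) were also among the 5 on the higher side. BLNK (identifier 109553167), the B cell linker adaptor, stood at 34.5 ± 3.03 against 82.1 ± 12.3 CPM (−1.25 ± 0.29), beside the B cell genes BCL11A (−1.26 ± 0.33) and BANK1 (−1.18 ± 0.31), the transcription factor TCF4 (−1.33 ± 0.35) and EIF2AK2, the interferon-induced kinase that senses double-stranded RNA (−1.59 ± 0.37). All 10 separated the 3 high-yielding from the 3 low-yielding cows. Since they were taken by lowest p in the same cows, this is no further support, and chance gives it for 10% of unselected genes. edgeR's quasi-likelihood test called 0 genes (lowest adjusted p = 0.353), with 1077 at an unadjusted p under 0.05 (625 higher, 452 lower). DESeq2 called 58 genes (48 higher, 10 lower) and limma-voom with sample weights 3908 (2411 higher, 1497 lower), of which 54 were shared. The voom weights ran from 0.184 for low 3 to 6.62 for low 2. Without low 3 the edgeR count was 2, ZNF74 and H1-2, which were chosen after their values were seen.

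Camera called 7 of 30 lists in Shweta Kapila, and 0 with an estimated correlation (lowest adjusted p = 0.718). NK and cytotoxic genes were higher (9 of 12, median 0.83; adjusted p = 0.000405, unadjusted p = 0.107 with an estimated correlation), including CST7 (1.35 ± 0.33), CTSW (1.78 ± 0.45, and 1.17 without high 1) and the activating receptor NCR3 (1.93 ± 0.50). T cell genes were higher (15 of 20, median 0.63; adjusted p = 0.000175, unadjusted p = 0.123 with an estimated correlation). Among them CD6 stood at 316 ± 103 against 141 ± 22.5 CPM (mean ± SD, n = 3 each; log2 fold change 1.17 ± 0.31), the receptor chain CD247 at 0.76 ± 0.21 and the kinase LCK at 0.89 ± 0.26. B cell genes were lower (12 of 13, median −0.88; adjusted p = 0.000175, unadjusted p = 0.161 with an estimated correlation), with FCRL1 at −1.13 ± 0.39. All 3 of these calls ended without low 3 (adjusted p = 0.246, 0.321 and 0.341). Cytosolic ribosomal protein genes were higher (74 of 75, median 0.58; adjusted p = 6.12e-10, unadjusted p = 0.222 with an estimated correlation), with RPL13A at 1.11 ± 0.45 and the short RPS29 at 3.84 ± 1.18 (1.74 and 4.84 without low 3). Oxidative phosphorylation genes were higher (56 of 70, median 0.48; adjusted p = 0.000338, unadjusted p = 0.326 with an estimated correlation), a call that ended without high 1 (0.323). In both lists high 3 and low 3 stood with the other yield class. Ribosomal genes were at a mean log2 CPM of 8.83, 8.69 and 7.72 in high 1 to high 3 and 7.54, 7.53 and 8.41 in low 1 to low 3. Oxidative phosphorylation genes were at 5.84, 5.43 and 4.75 against 4.71, 4.77 and 5.33. Over the 12 cows 46 of the 75 ribosomal and 34 of the 70 oxidative phosphorylation members correlated negatively with component 1 at an unadjusted p under 0.05 (0 and 7 positively). Both of these lists turned to the lower side when the share of the unnamed short identifiers, 6.09 ± 2.52% in high-yielding and 10.1 ± 3.98% in low-yielding cows, was a covariate (adjusted p = 0.462 and 0.308).

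Interferon response genes were lower in high-yielding Shweta Kapila cows (23 of 33, median −0.43; camera adjusted p = 0.00144, unadjusted p = 0.253 with an estimated correlation), with the antiviral GTPases MX2 at −1.72 ± 0.53 and MX1 at −1.01 ± 0.37. That call held with each cow left out, but only just without low 1 (camera adjusted p = 0.0499). The interferon call ended with the share covariate (0.135). It also ended without the 3 libraries of over 22 M counts, where low-yielding Shweta Kapila is down to a single cow. Heat shock genes were lower (16 of 22, median −0.39; adjusted p = 0.0276, unadjusted p = 0.318 with an estimated correlation), with the mitochondrial chaperone HSPA9 at −0.71 ± 0.28, and CRYAB on the other side at 1.93 ± 0.87. Of the 22 members 13 correlated positively with component 1 at an unadjusted p under 0.05 (2 negatively). This call ended without high 2 (0.267), low 1 (0.241) or low 2 (0.151), and without the 3 largest libraries (0.957), and turned with the share covariate (0.572). Adjusted over the list alone, 15 memberships passed where 0 passed over all genes, namely 5 of the NK list, 3 of the T cell list, 2 each of the B cell, dendritic and inflammatory lists and 1 of the interferon list. The B cell and dendritic lists share BLNK, so their results are not separate. The T cell list score differed by 0.52 log2 units and the dendritic cell score by −0.36, each at the smallest p the exact permutation test allows (p = 0.1, adjusted p = 0.5 over 10 lists).

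Averaged over both breeds, CPT1A (log2 fold change 0.94 ± 0.23) was among the 5 named genes of lowest p on the higher side and the interferon-induced kinase EIF2AK2 (−0.89 ± 0.26) on the lower. KCNT1, a sodium-activated potassium channel (1.15 ± 0.24), DCSTAMP, a fusion protein of osteoclast and dendritic lineages (3.12 ± 0.68), RGS9 (1.12 ± 0.25) and SLC14A1 (1.15 ± 0.27) completed the higher side. DCSTAMP stood at 41.6 ± 26.5 against 5.62 ± 1.71 CPM in Gir and 29.3 ± 36.3 against 2.88 ± 0.853 CPM in Shweta Kapila (mean ± SD, n = 3 each). Its log2 fold change was 2.25 without Shweta Kapila high 1. RGS9, SLC14A1 and EIF2AK2 differed mostly in Shweta Kapila. RGS9 stood at 23.9 ± 3.48 against 23.2 ± 10.4 CPM in Gir and 62.9 ± 4.83 against 13.8 ± 4.61 CPM in Shweta Kapila (mean ± SD, n = 3 each). SLC14A1 stood at 1.70 ± 0.230 against 1.64 ± 0.441 CPM and 3.82 ± 0.679 against 0.801 ± 0.244 CPM. The log2 fold change of EIF2AK2 was −0.19 in Gir and −1.59 ± 0.37 in Shweta Kapila. NRIP3 (−1.13 ± 0.27), CD24 (−0.92 ± 0.25), AOAH, the hydrolase that inactivates lipopolysaccharide (−0.63 ± 0.18), and heparanase HPSE (−0.73 ± 0.21) were on the lower side. edgeR's quasi-likelihood test called 0 genes (lowest adjusted p = 0.874), with 637 at an unadjusted p under 0.05 (351 higher, 286 lower) where uniform p-values would give 771. DESeq2 called 4, all higher and all also called by voom, which called 1289. The 4 were KCNT1, DCSTAMP, LOC109566689 and PPIC, the last chosen after its values were seen. Adjusted over the list alone, 1 membership passed, CPT1A in the fatty acid list.

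Camera called 3 lists for yield over both breeds, and 0 with an estimated correlation (lowest adjusted p = 0.736). Interferon response genes were lower with high yield (27 of 33, median −0.34; adjusted p = 3.08e-05, unadjusted p = 0.135 with an estimated correlation), including RSAD2 (−0.79 ± 0.26) and MX1 (−0.77 ± 0.26), and the call held with each cow left out. B cell genes were lower (13 of 13, median −0.52; adjusted p = 0.00027, unadjusted p = 0.17 with an estimated correlation), including BANK1 (−0.63 ± 0.22), the B lineage factor EBF1 (−0.75 ± 0.28) and BLNK (−0.52 ± 0.20), and this call ended without Shweta Kapila low 3 (0.248). Ribosomal protein genes were higher (68 of 75, median 0.23; adjusted p = 0.000218, unadjusted p = 0.417 with an estimated correlation), a call that ended without Shweta Kapila high 1 (0.0572) and turned with the share covariate (0.212). None of the members passed over all genes or adjusted over the list alone (0 calls). The list count became 5 without Gir high 3, Gir low 1, Gir low 2 or Shweta Kapila high 3, and 7 without Shweta Kapila high 2 or low 1.

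The yield differences of the 2 breeds were then set against each other. PRF1 was at 71.1 ± 24.0 against 97.5 ± 39.3 CPM for high and low yield in Gir and at 359 ± 107 against 113 ± 9.81 CPM in Shweta Kapila (mean ± SD, n = 3 each), a log2 difference of −2.13 ± 0.50. CCL5 (−3.48 ± 0.83), BEGAIN (−4.25 ± 0.94), the calcium pump ATP2B2 (−1.97 ± 0.44) and RGS9 (−2.14 ± 0.50) shared that side. CCL5 was at −2.76 without Shweta Kapila high 1 and BEGAIN at −3.32 without high 2. The other side held PDK4 (2.57 ± 0.66), BLNK (1.47 ± 0.40), FCER2, the low-affinity IgE receptor of B cells (2.00 ± 0.56), RADX, a protein of replication forks (2.13 ± 0.54), and C23H6orf132 (3.90 ± 0.85, and 4.58 without Gir low 2 or 4.65 without Shweta Kapila high 2). edgeR's quasi-likelihood test of the interaction called 0 genes (lowest adjusted p = 0.955), with 587 at an unadjusted p under 0.05 (225 higher, 362 lower) where uniform p-values would give 771. DESeq2 called 8 and voom 1321, with 7 shared. Without Shweta Kapila low 1 edgeR called 1 gene, TMTC2, which was chosen after its values were seen. Adjusted over the list alone 9 memberships passed, 5 of them in the NK list. Across the 15420 genes, which are not independent, the yield difference in Gir and that in Shweta Kapila correlated at r = 0.0333 (rho = 0.0574), and 344 of 400 labelings within breed gave a correlation as large (exact permutation p = 0.86).

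Camera called 12 lists for the breed difference in the yield effect, and 0 with an estimated correlation (lowest adjusted p = 0.342). T cell and NK genes were among the strongest. T cell genes were lower for Gir minus Shweta Kapila (18 of 20, median −0.91; adjusted p = 4.67e-06, unadjusted p = 0.0743 with an estimated correlation), with LCK at −1.13 ± 0.37 and CD247 at −1.03 ± 0.29. NK genes were lower (10 of 12, median −1.05; adjusted p = 2.88e-05, unadjusted p = 0.0652 with an estimated correlation), with NKG7 at −2.11 ± 0.67. Both calls held with each cow left out. Pattern recognition receptor genes stood on the higher side (16 of 20, median 0.48; adjusted p = 0.00129, unadjusted p = 0.0707 with an estimated correlation), with TLR7 at 1.28 ± 0.50 and TLR2 at 1.13 ± 0.47. In the exact permutation test over 400 labelings the list scores differed by 0.57 for dendritic cells (p = 0.04), −0.71 for T cells (p = 0.06) and −1.23 for NK cells (p = 0.07), each with an adjusted p of 0.233 over 10 lists. These labelings stand for no yield effect in either breed, so the p-values do not test the breed difference alone. The dendritic list shares BLNK with the B cell list.

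**Figure D3:**
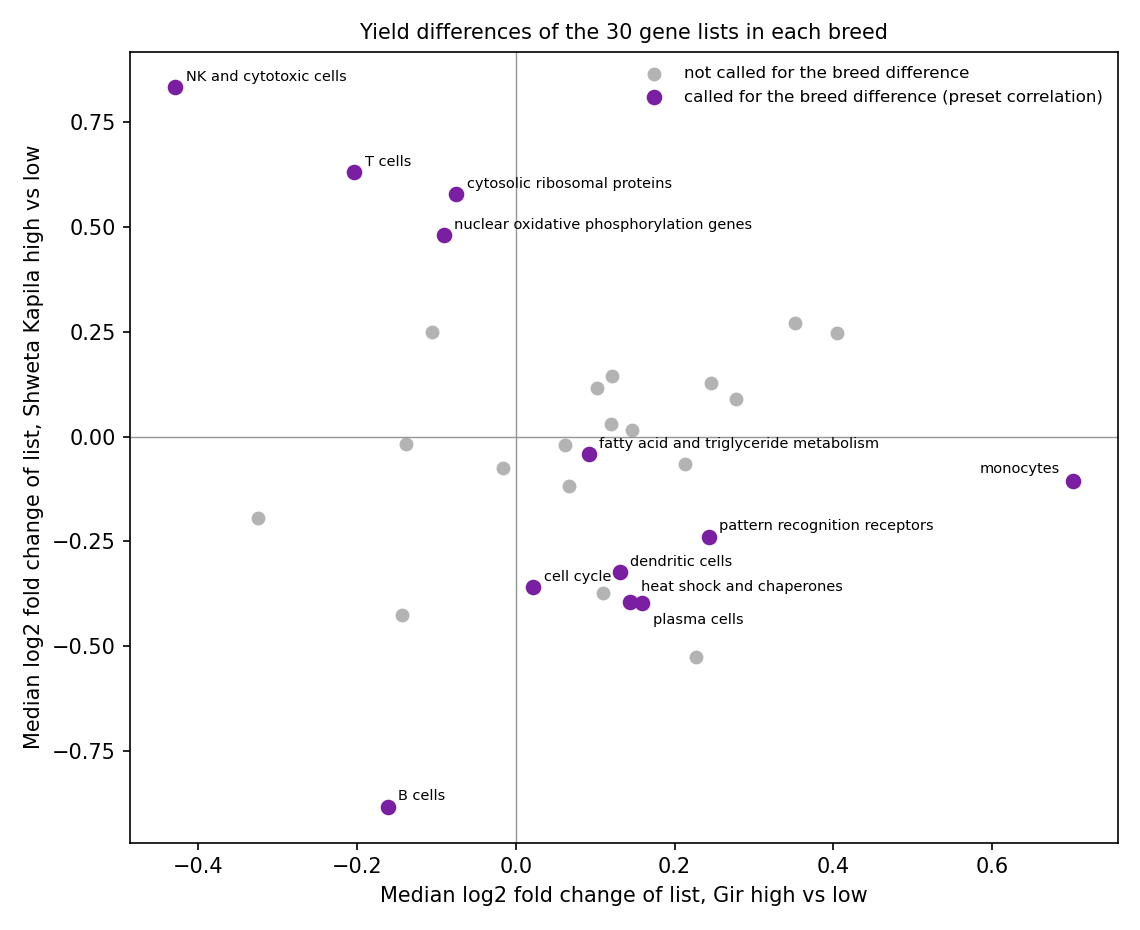
Median log2 fold change of each of the 30 gene lists for high against low yield in Gir (horizontal axis) and in Shweta Kapila (vertical axis); purple points are the 12 lists called by camera at the preset correlation for the breed difference, none of which was called with an estimated correlation. NK genes lie at −0.43 in Gir and 0.83 in Shweta Kapila, and T cell genes at −0.20 and 0.63.

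Between the breeds, PRF1 and S1PR5 were among the 5 named genes of lowest p on the side lower in Gir. The labels name no batch, so breed differences cannot be told apart from any in keeping or processing that go with breed. PRF1 differed by −1.28 ± 0.25 and S1PR5, a sphingosine phosphate receptor that guides NK cell exit from tissue, by −1.40 ± 0.26. KCNK1, a potassium channel, stood at 3.22 ± 0.294 and 3.42 ± 0.467 CPM in high-yielding and low-yielding Gir and at 10.1 ± 1.24 and 7.98 ± 2.98 CPM in the Shweta Kapila groups (mean ± SD, n = 3 each; log2 fold change −1.44 ± 0.22). ABHD15 (−1.64 ± 0.31) and ATP2B2 (−1.09 ± 0.22) were lower as well. Higher in Gir were DMBT1, a scavenger receptor of mucosal defence (2.00 ± 0.34), the muscle calpain CAPN3 (1.35 ± 0.24), SIGLEC1, the interferon-induced sialoadhesin of monocytes (2.05 ± 0.40), TTC21B, a ciliary transport gene (1.01 ± 0.21), and the phosphatase PTPRO (1.53 ± 0.33). edgeR's quasi-likelihood test called 0 genes, although 8 had an adjusted p under 0.1 (lowest 0.0896; KCNK1 0.0985), and 1476 had an unadjusted p under 0.05 (583 higher, 893 lower). DESeq2 called 185 (62 higher, 123 lower) and voom 2580 (1475 higher, 1105 lower), with 175 shared. Without Shweta Kapila low 3 edgeR called 447 genes (202 higher, 245 lower).

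Leaving out other cows moved the breed count less. It was 4 without Shweta Kapila high 3 (LOC109559508, LOC109559513, LOC109559668 and HAP1) and 3 without high 1 (LOC109559508, LOC109559668 and CRYBA1). It was 2 without low 2 (LOC109559668 and LOC109577299), 2 without Gir low 2 (LOC109571678 and LOC109575720) and 1 without Gir high 3 (COL11A1). These genes were named after their values were seen, except LOC109559508, LOC109559668 and LOC109571678. LOC109559668 differed by −2.44 ± 0.32, LOC109559508 by −2.44 ± 0.36 and LOC109571678 by 5.39 ± 0.89.

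Camera called 12 lists between the breeds, and 0 with an estimated correlation (lowest adjusted p = 0.463). NK and cytotoxic genes were lower in Gir (11 of 12, median −0.67; adjusted p = 6.94e-05, unadjusted p = 0.0632 with an estimated correlation), and 7 members passed adjusted over the list alone, including the granzyme GZMA (−1.93 ± 0.57, and −0.42 without the 3 largest libraries), NKG7 (−1.14 ± 0.33) and the transcription factor TBX21 (−0.51 ± 0.16). T cell genes were lower (15 of 20, median −0.43; adjusted p = 0.00495, unadjusted p = 0.217 with an estimated correlation), and 4 passed adjusted over the list alone, namely CD6 (−0.91 ± 0.22), CD8A (−1.31 ± 0.33), CD8B (−0.85 ± 0.26) and CD3G (−1.12 ± 0.33). Neutrophil genes were higher (15 of 16, median 0.46; adjusted p = 0.000224, unadjusted p = 0.0621 with an estimated correlation), with alkaline phosphatase ALPL at 1.14 ± 0.34, PGLYRP1, a granule protein, at 1.73 ± 0.65, and TREM1 at 0.62 ± 0.25. Of the 16 members 9 correlated negatively with component 1 at an unadjusted p under 0.05 (0 positively). Interferon genes were higher (26 of 33, median 0.21; adjusted p = 0.000567, unadjusted p = 0.208 with an estimated correlation), with MX2 at 1.37 ± 0.37 and EPSTI1 on the other side at −0.55 ± 0.16, and 1 passed adjusted over the list alone, SIGLEC1. The NK, neutrophil and interferon calls held with each cow left out. The T cell call ended without Gir low 3 (0.0631), and the T cell and neutrophil calls ended without the 3 libraries of over 22 M counts (0.595 and 0.0631). In the exact permutation test over 924 assignments the neutrophil list score differed by 0.58 log2 units (p = 0.0173, adjusted p = 0.173) and the NK score by −0.81 (p = 0.0411, adjusted p = 0.206). Without Shweta Kapila low 3 the count of scores past the threshold went from 0 to 5, and without high 1 to 1, the neutrophil score.

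Glycolysis genes were higher in Gir than in Shweta Kapila cows (16 of 21, median 0.20; camera adjusted p = 0.00517, unadjusted p = 0.207 with an estimated correlation), with the fructose bisphosphate regulators PFKFB4 at 0.75 ± 0.25 and PFKFB3 at 0.58 ± 0.23. Oxidative phosphorylation genes were lower (57 of 70, median −0.24; adjusted p = 0.00495, unadjusted p = 0.412 with an estimated correlation), with NDUFS4 at −1.04 ± 0.26 and SDHC on the other side at 0.63 ± 0.21. Unfolded protein response genes were lower (17 of 22, median −0.31; adjusted p = 0.00961, unadjusted p = 0.141 with an estimated correlation), with XBP1 at −0.47 ± 0.17, and so were class I antigen presentation genes (11 of 12, median −0.22; adjusted p = 0.0304, unadjusted p = 0.138 with an estimated correlation), with B2M at −0.45 ± 0.19. B cell (11 of 13, median 0.34; adjusted p = 0.0277), pattern recognition (15 of 20, median 0.22; 0.0294), monocyte (7 of 9, median 0.32; 0.0432) and platelet genes (13 of 14, median 0.46; 0.0435) were higher, with unadjusted p-values of 0.364, 0.174, 0.231 and 0.194 with an estimated correlation. Of the 21 glycolysis members 15 correlated negatively with component 1 at an unadjusted p under 0.05 (1 positively). For oxidative phosphorylation these counts were 34 of 70 (7 positively), and for the unfolded protein response 1 of 22 (9 positively). The glycolysis and unfolded protein calls held with each cow left out, but without the 3 largest libraries glycolysis lost its call (0.61) and the unfolded protein list turned (0.863). Both calls ended with the total count as a covariate (0.107 and 0.0782). No member of these 8 lists passed over all genes or adjusted over the list alone (0 calls).

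The remaining breed calls each ended with several of the cows left out in turn. That of oxidative phosphorylation ended without Gir low 3 (0.0601), Shweta Kapila high 1 (0.41) or low 3 (0.295), and that of class I genes without Gir high 1 (0.0585), Gir low 3 (0.0773), Shweta Kapila high 1 (0.255) or low 3 (0.128). The B cell call ended without Gir high 3 (0.0619), Gir low 3 (0.15), Shweta Kapila high 1 (0.0885) or low 1 (0.232), and with the total count as a covariate (0.173), and turned without the 3 largest libraries (0.58). The pattern recognition call ended without Gir high 3 (0.0682), Gir low 3 (0.0929), Shweta Kapila high 1 (0.0885), high 2 (0.0889) or low 3 (0.325). The monocyte call ended without any of Gir high 2, high 3, low 1 and low 3 and Shweta Kapila high 1, high 2 and low 3 (0.0542 to 0.403). The platelet call ended without any of Gir high 1, high 2, low 2 and low 3 and Shweta Kapila high 1, high 2, low 1 and low 3 (0.0514 to 0.393), at a prior count of 0.5 (0.0571) and without the 37 unnamed identifiers (0.0539). The list count of 12 became 5 without Gir low 3 and 6 without Shweta Kapila high 1.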

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

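The tests with a covariate and of the CD3 genes were chosen only after the lists had been seen. For 12 of the 30 lists the yield difference in Gir departed from that in Shweta Kapila, by camera on the interaction term at the preset correlation. For none of the 12 was the call kept with an estimated correlation (lowest adjusted p = 0.342).

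Lower for the Gir difference minus the Shweta Kapila difference were cytosolic ribosomal protein genes (camera adjusted p = 2.2e-10, unadjusted p = 0.213 with an estimated correlation; medians −0.07 in Gir and 0.58 in Shweta Kapila), T cell genes (4.67e-06), NK and cytotoxic genes (2.88e-05) and oxidative phosphorylation genes (7.2e-05, unadjusted p = 0.289 with an estimated correlation), the last with a call that ended without Shweta Kapila high 1 (0.0524). The ribosomal and oxidative phosphorylation lists turned to the other side with the share of the unnamed short identifiers as a covariate (both adjusted p = 0.627).

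Higher were heat shock genes (camera adjusted p = 0.000401, unadjusted p = 0.158 with an estimated correlation), pattern recognition receptors (0.00129), monocyte genes (0.00263, unadjusted p = 0.103 with an estimated correlation; CD14 1.01 ± 0.53) and dendritic cell genes (0.00535, unadjusted p = 0.0234 with an estimated correlation; FLT3 1.38 ± 0.55), the last ending without Shweta Kapila low 3 (0.129). B cell genes (0.00535, unadjusted p = 0.289 with an estimated correlation; BANK1 1.09 ± 0.44) lost their call without Shweta Kapila high 3 (0.0782) or low 3 (0.617). Cell cycle genes (0.0224, unadjusted p = 0.397 with an estimated correlation) lost it without Gir high 1, low 1 or low 3 or Shweta Kapila high 3, low 1 or low 2 (0.0687 to 0.443). Plasma cell genes (0.0265, unadjusted p = 0.0599 with an estimated correlation; SDC1 5.41 ± 1.42, and 3.62 without Gir high 1 or 4.28 without Shweta Kapila low 3) lost it without Gir low 2 or low 3 or Shweta Kapila high 3 or low 3 (0.0785 to 0.381). Fatty acid genes (0.0289, unadjusted p = 0.0797 with an estimated correlation) lost it without Gir high 3 or low 2 or Shweta Kapila high 2 or low 3 (0.0549 to 0.161). Of these calls those of heat shock (0.311), monocyte (0.0676) and fatty acid genes (0.214) also ended without the 3 libraries of over 22 M counts, where the cell cycle list turned and was called lower (0.0122), and those of heat shock (0.772), pattern recognition (0.327), monocyte (0.43), cell cycle (0.44) and fatty acid genes (0.627) with the share covariate.

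T cell and NK lists differed between the breeds in their yield effect, with medians of −0.20 and −0.43 in Gir and 0.63 and 0.83 in Shweta Kapila. In Gir the NK list was not called (camera adjusted p = 0.0823) and the T cell call ended without any of 6 cows (0.0522 to 0.65), so a lower level with high yield in Gir is not established. The NK list kept its camera call with the log2 total count as a covariate (adjusted p = 6.35e-06, median −1.18) and with the log2 share of the unnamed identifiers (adjusted p = 0.000244, median −1.34), against a median of −1.05 without either. T cell medians were −0.86 and −0.81 against −0.91. The calls cannot decide on sequencing depth or the share, since at the preset correlation arbitrary splits of the cows called lists too. Without the 3 libraries of over 22 M counts, where low-yielding Shweta Kapila is down to a single cow, the medians were −2.33 for NK and −1.31 for T cells. A different effect of yield on the blood share of T and NK cells in each breed stays open. That 4 of 4 CD3 genes lay on the same side decides nothing, as they belong to the T cell list itself (CD3D −0.90 ± 0.44, CD3E −0.92 ± 0.35, CD3G −1.33 ± 0.65, or −2.02 without Shweta Kapila low 1, and CD247 −1.03 ± 0.29), the first 3 of them chosen after their values were seen. A change of expression within the cells stays open as well, as does an untested difference between the breeds. So does the placement of Shweta Kapila low 3. Without that cow the camera calls within Shweta Kapila were lost (adjusted p = 0.321 for T cells and 0.246 for NK cells). The camera calls for the breed difference then held (adjusted p = 0.0406 for both lists). Chance cannot be excluded, since 7 of 100 splits of the cows gave 12 or more called lists (highest other split 16).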

How the results depend on the processing

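The fits without the 37 unnamed identifiers, with thinned counts, without the 3 largest libraries and with a covariate were chosen only after the data had been seen; the others were fixed before the data were examined. Planned fits without haemoglobin genes and without mitochondrially encoded and ribosomal RNA genes were not run, since the tables used here do not name those genes. The edgeR counts of 0 genes stayed at 0 under both other scalings, the stricter filter, the fold minimum, the fit on each breed alone (yield within that breed), thinning and the removal of the unnamed identifiers, beside 291, 1077, 637, 587 and 1476 genes at an unadjusted p under 0.05. Uniform p-values would give 771 in each comparison. The cause of the differences below was not tested. DESeq2 called 1 gene for yield in Gir, 58 in Shweta Kapila, 4 over both breeds, 8 for the interaction and 185 between breeds, and limma-voom with sample weights 1, 3908, 1289, 1321 and 2580. Without the 3 libraries of over 22 M counts edgeR called 3 genes for yield in Shweta Kapila (RGS5, LOC109575648 and an unnamed identifier), 1 over both breeds (LOC109575648) and 31 between breeds; low-yielding Shweta Kapila then has 1 cow, which is assumed to vary like the other groups. With the log2 total count as a covariate it called 1 in Shweta Kapila (an unnamed identifier) and 53 between breeds, and with the log2 share of the unnamed identifiers 33 between breeds. Without a filter it called 3 between breeds (COL11A1, LOC109559508 and LOC109559668). Of the genes in these counts of 5 or fewer, those not named elsewhere were chosen after their values were seen. With each cow left out the gene count ran from 0 to 0 in Gir, 0 to 2 in Shweta Kapila, 0 to 0 over both breeds, 0 to 1 for the interaction (1 without Shweta Kapila low 1) and 0 to 447 between breeds (447 without Shweta Kapila low 3).

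The number of lists called by camera (6, 7, 3, 12 and 12) was 0 in all 5 comparisons with an estimated correlation and 0 by fry, whose mixed test called 4 between breeds (NK, T cell, dendritic cell and milk synthesis lists). With each cow left out it ran from 3 to 10 in Gir, 5 to 10 in Shweta Kapila, 2 to 7 over both breeds, 9 to 16 for the interaction and 5 to 16 between breeds. It was 8 over both breeds without the 3 largest libraries, and with the share covariate 4 in Shweta Kapila and 5 for the interaction. In camera with the share covariate ribosomal genes turned in Shweta Kapila (adjusted p = 0.462), over both breeds (0.212) and for the interaction (0.627), oxidative phosphorylation genes in Shweta Kapila (0.308) and for the interaction (0.627), and heat shock genes in Shweta Kapila (0.572). Without the 3 largest libraries cell cycle genes turned for the interaction (0.0122), and unfolded protein response (0.863) and B cell genes (0.58) between breeds, as did BUB1B for the interaction (log2 −0.14) and HSP90B1 (0.13), TLR3 (0.12) and RAB27B (0.30) between breeds. The named genes otherwise kept their direction in every alternative run. Of the cell type scores 0 passed in each comparison, and with a cow left out 0 to 5 between breeds (5 without Shweta Kapila low 3, 1 without high 1).

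The replicate numbers name different cows. Deviations of cows with the same number correlated between −0.0635 and 0.00627 in Gir and between −0.558 and −0.134 in Shweta Kapila, and 3 of the 18 pairs over all groups were above 0.1, so the numbers do not pair the samples. With the replicate block edgeR called 1 gene between breeds (LOC109566163) and camera 5 lists over both breeds. Depth limits low genes, since 1 count equals 0.0704 CPM in the smallest library, while thinning to that library left every edgeR count at 0.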

Other observations

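The tests of cell type shares, exchanged labels and gene span were chosen only after the placement of the cows on component 1 had been seen.

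Camera did not call the milk synthesis list (23 members measured) in blood. It came closest between breeds, higher in Gir for 17 members and lower for 6 (median 0.17, camera adjusted p = 0.0786), where the mixed test of fry, which takes members of either direction, called it (adjusted p = 0.0454), and its camera adjusted p for yield was 0.692 in Gir and 0.906 in Shweta Kapila. Growth hormone, insulin and mTOR signalling genes had medians of −0.02 for yield in Gir and −0.07 in Shweta Kapila (camera adjusted p = 0.513 and 0.652). Of the other lists that camera never called, the lowest camera adjusted p over the 5 comparisons was 0.0658 for erythroid genes (9 of 11 higher in Gir than in Shweta Kapila), 0.0823 for antioxidant, 0.0839 for glucocorticoid and 0.0839 for immediate early genes, 0.0857 for sterol synthesis, 0.0948 for complement and 0.12 for eosinophil and basophil genes, all for yield in Gir, and 0.123 for class II antigen presentation with 4 members measured. The calcium list had a lowest adjusted p of 0.237.

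Single members of lists that camera did not call in that comparison also stood apart. LAMP3, a lysosomal protein of mature dendritic cells, was at 410 ± 24.3 and 470 ± 15.3 CPM in the Gir groups and 632 ± 107 and 711 ± 193 CPM in the Shweta Kapila groups (mean ± SD, n = 3 each; log2 fold change −0.61 ± 0.16), and passed adjusted over the list alone, the only lower member of the dendritic list against 9 higher. The cytokine gene TNF was at 41.6 ± 11.5 CPM in high-yielding and 18.2 ± 2.46 CPM in low-yielding Shweta Kapila cows (1.19 ± 0.28) and passed adjusted over the list alone, with CCL5, in an inflammatory list whose members went both ways (11 higher, 14 lower). In edgeR's test over all genes neither passed (adjusted p = 0.291 and 0.575). LAMP3 was also the dendritic member of highest correlation with component 1 over the cows (r = 0.740).

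Component 1 placed Shweta Kapila high 3 (45.6) with low 1 (104) and low 2 (63.7), and low 3 (−54.3) with high 1 (−62.4) and high 2 (−13.0). After thinning every library to the smallest total, component 1 scores correlated at 0.99998 in size with the original ones. The number of counts drawn thus does not by itself make the placement. Thinning cannot undo a difference between libraries that goes with depth. Within Shweta Kapila the scores correlated with the total count at r = 0.888, which did not pass (exact permutation, adjusted p = 0.0708). An exchange of the labels of high 3 and low 3 and a batch of libraries cannot be told apart. Of the 10 splits of the 6 cows the one that exchanges them gave 7379 genes at an unadjusted p under 0.05 in edgeR's test (highest other split 2584, deposited labels 1077), but this split is the one component 1 itself makes, and it also parts the 3 libraries of over 22 M counts from the rest, so its count supports neither. The count columns of the Shweta Kapila cows are numbered 1 to 5 and 7 in the labels. Low 3 is number 7 and was matched by its label alone. The component 1 loading correlated with log gene span over 14012 genes, which are not independent (Spearman rho = 0.362), as a difference in unspliced or degraded RNA may give. The ribosomal and oxidative phosphorylation lists, which follow component 1, have median spans of 3.69 and 7.27 kb against 22.6 kb over all genes with a span. Shares of the listed cell types stay open, since 2 of the 10 lists, T cells and plasma cells, held members that follow component 1 in both directions, a number between the bounds set for the test. Neutrophil members past that bound (unadjusted p under 0.05) lay on 1 side only (9 of 16 negatively, 0 positively). So did those of B cells (4 of 13), eosinophils and basophils (3 of 10) and erythroid cells (2 of 11), all negatively. Without the share over all genes these counts do not set a list apart. No other biological explanation was tested.

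Other splits of the cows were counted for each comparison. For the breed difference in the yield effect, splits within breed stand for no yield effect in either breed, not for an equal effect in both. For yield within a breed the 10 splits are too few for a share under 0.05, with 291 genes at an unadjusted p under 0.05 in Gir (highest other split 366; 2 of 10 as large) and 1077 in Shweta Kapila (highest other 7379; 4 of 10), and with 6 called lists in Gir (highest other 14; 5 of 10) and 7 in Shweta Kapila (highest other 12; 4 of 10). For yield over both breeds 30 of 100 splits within breed gave 637 genes or more (highest other 6572) and 90 of 100 gave 3 lists or more (highest other 14), so chance is not excluded. Nor is it for the breed difference in the yield effect, where 36 of 100 splits gave 587 genes or more (highest other 6098), or between breeds, where 17 of 100 splits within yield class gave 1476 genes or more (highest other 4865) and 9 of 100 gave 12 lists or more (highest other 17). The other splits called a median of 5 or 6 lists in every comparison, so several list calls at the preset correlation are common under arbitrary splits of these cows. Splits that called several times the real number of genes point to a structure of the Shweta Kapila samples that their yield labels as deposited do not follow.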
